A study of Homo sapiens with 9 samples.

How the data were processed

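RNA of LNCaP cells, a human prostate adenocarcinoma line, was measured on 9 one-colour microarrays, 3 in each of 3 groups. Per the series' design text, the cells overexpressed a control, BHC80-1 or BHC80-2 from a lentivirus and were cultured for 48 hours in RPMI medium. BHC80-1 and BHC80-2 are read here as isoforms of BHC80, the protein encoded by PHF21A. The replicate numbers and groups were taken from the labels. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples.

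The deposited scanner files hold linear spot intensities, made by the authors with Agilent Feature Extraction 11.0.1.1 and its one-colour gene expression protocol, per the file headers. The processed intensity is the spot signal after subtraction of local background and spatial detrending, with no scaling between arrays, per the file headers. Median pixel intensities of the spots and of their local background were also deposited, per the file headers, and served in 1 alternative. The files hold no mean pixel intensity for this design, so the median took its place there. Each array held 58717 non-control spots for 50599 probes. A series-wide deposited table was used for probe annotation alone, and its 27 columns of values named only by a number were left out because nothing pairs them with samples.

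The precision is limited by the 3 arrays per group. The 75th percentile of the processed intensity ran from 377.4 on control array 2 to 999.5 on control array 1. Between 56.7% and 65.3% of non-control spots were well above background by the software's flag, and no spot was saturated. The median coefficient of variation between spots of the same probe lay between 3.03% and 3.46%. The 9 arrays lay on 2 slides, with each group on both. Slide 1 held control arrays 1 and 3, BHC80-1 arrays 1 and 2 and BHC80-2 array 3.

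The normalization, filters, tests, thresholds, gene lists, rule for named genes and all other settings tried, apart from those stated, were chosen before the data were examined. The lower bounds on folds, the updating of gene names and the use of median pixel intensities were settled afterwards. Control spots and spots called non-uniform or population outliers (203 to 351 per array) were dropped. The log2 of the processed intensity was reduced by the array's 75th percentile over non-control probes, and spots of a probe were averaged. Values are normalized log2 intensities on this scale. Probes well above background on at least 3 of the 9 arrays were tested, which left 30384 probes. One limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes) of all 9 arrays, with a mean per group and 6 residual degrees of freedom, gave log2 fold changes, standard errors (SE) and p-values for the 3 comparisons. The named genes were ranked by estimated log2 fold change, including those given with a lower bound. P-values were adjusted by the Benjamini-Hochberg method over the tested probes, with a threshold of 0.05. Each of the 18659 genes was represented by its brightest tested probe. Counts with a fold change of at least 2 are also given. Where no array of a group was well above background, the fold is a lower bound. For it, that group's values were raised to each array's lowest value that was well above background, and the fold is written as "at least". Coordinates are those of the probes in the deposited annotation, and the grid build is hg19 per the file headers. Gene names were updated through Entrez identifiers (33229 probes) or accessions (57 probes) to a RefSeq table of GRCh38.p14, used for names alone. For 8382 probes the name in the file was absent from that table and was kept, for 30 it was kept as found, and 8901 probes had no name.

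In each comparison the rule for named genes took PHF21A, the 8 largest rises and 8 largest falls among genes past the threshold whose arrays did not overlap between groups and that have an approved-style symbol, and up to 2 members with the smallest p in each gene list. Of the genes this rule takes, some are not reported. KLK2, KLK3, VIM, COL1A1, LGALS1 and CCDC80 were named after their values were seen, as were the gene families of the closing section. The 21 gene lists, from textbook knowledge, were androgen receptor targets, neuroendocrine markers, REST target neuronal genes, cytokines and chemokines, immediate early and labile transcripts, NF-kappaB targets, Toll-like receptor, MyD88 and p38 components, interferon-stimulated genes, LSD1-CoREST complex and partners, mitosis, DNA replication, p53 targets, ATF4 and unfolded protein response, hypoxia targets, cholesterol synthesis, epithelial-mesenchymal transition, luminal epithelial markers, basal epithelial markers, fibroblast and stromal markers, leukocyte markers and neural splicing regulators. Lists were tested with limma's camera, which compares a list with all other genes, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over the 63 tests of 21 lists in 3 comparisons.

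The changes of both isoforms against control were correlated across genes and set against 1000 simulated pairs of unchanged groups that share their control arrays. The 3 control arrays cannot be split into independent controls with replicates. On data simulated for BHC80-1 versus control with 30384 probes and 200 changed genes, the scripts recovered 40% of the genes changed 1.5-fold and 79% of those changed 2-fold. They called 4 unchanged probes there, and ranked the 1 shifted list first. In the data 13266 probes passed in that comparison. The adjustment was therefore less strict there than in the simulation, and the recovered shares do not carry over.

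The other settings tried were the 75th percentile over probes detected on all arrays, median centring, quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, a filter requiring all 9 arrays, outlier spots kept, the mean of the probes of a gene, an intensity trend in the variance, a fit of only the groups compared, the replicate number as a block, the slide as a block, a 2-fold threshold, each array left out in turn and the estimated correlation. Fits of slide 1 alone and slide 2 alone were added after the data had been seen. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.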

Results

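Gene expression was measured in LNCaP cells, a human prostate adenocarcinoma line that depends on the androgen receptor, after lentiviral overexpression of a control, BHC80-1 or BHC80-2. BHC80, encoded by PHF21A, is a partner of the histone demethylase LSD1 and its corepressor CoREST. Each group had 3 arrays, and each array 58717 non-control spots, of which 56.7% to 65.3% were well above background. The series' title places the work in the study of RNA splicing of BHC80 and neuroendocrine prostate cancer. Values are normalized log2 intensities given as mean ± SD (n = 3 arrays), and changes are log2 fold changes ± SE from limma with 3 arrays per group. Profiles correlated at 0.987 to 0.990 among control arrays, at 0.992 to 0.994 within either BHC80 group, at 0.990 to 0.993 between the BHC80 groups and at 0.965 to 0.974 between BHC80 and control arrays, across genes, which are not independent replicates.

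PHF21A was higher in both BHC80 groups. Its only probe, A_33_P3346473 (chromosome 11, 45950945 to 45951004, hg19), read −0.82 ± 0.08 in control, 0.27 ± 0.11 with BHC80-1 and 0.11 ± 0.15 with BHC80-2. The change was 1.09 ± 0.10 (2.13-fold, adjusted p = 6.47e-05) for BHC80-1 and 0.93 ± 0.10 (1.9-fold, adjusted p = 0.000144) for BHC80-2. BHC80-2 differed from BHC80-1 by −0.17 ± 0.10 on this probe, which did not pass the test (adjusted p = 0.524). A single probe cannot tell the isoforms apart, and whether it lies in the introduced sequence is not known from the files.

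The comparison of BHC80-1 with control asks which genes differ when this isoform is overexpressed. Of 18659 tested genes, 4004 were higher and 4814 lower (8818 in all, 47.3%), and 1470 of the higher and 681 of the lower changed at least 2-fold. The cancer-testis antigen genes CTAG2 and CTAG1A, close paralogs whose probes may share signal, rose most, by 7.19 ± 0.09 (146-fold, adjusted p = 1.58e-08) and 7.16 ± 0.08 (142.8-fold). CTAG2 (X chromosome, 153880418 to 153880477) went from −1.46 ± 0.17 to 5.73 ± 0.07. By estimated change, which places genes whose control is below background only roughly, the next rises were those of the Wnt pathway transcription factor TCF7L1 (at least 9.92-fold higher), the matrix protein gene NPNT (4.56 ± 0.34), the neutrophil chemokine CXCL2 (at least 6.01-fold), LAMP3 (at least 5.63-fold), the teneurin TENM2 (4.46 ± 0.11) and IL12A, a subunit of an interleukin (at least 6.22-fold). Ranked in the same way, the falls were led by those of the mitochondrial co-chaperone gene DNAJC15 (at least 42.2-fold lower), the aldehyde dehydrogenase gene ALDH7A1 (−7.56 ± 0.39), the adaptor SHC3 (−5.36 ± 0.14), CPNE4 (at least 7.97-fold lower), the trefoil factor TFF1 (−4.56 ± 0.09), the protocadherin PCDHB5 (−4.42 ± 0.10), the sialidase NEU4 (−3.95 ± 0.25) and COLCA1 (−3.86 ± 0.10). TFF1 (chromosome 21, 43783440 to 43783499) went from 4.78 ± 0.05 to 0.22 ± 0.13. Among the rises, NPNT was well above background on only 1 of the 3 control arrays, so its size and rank are rough too.

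The comparison of BHC80-2 with control asks the same of the other isoform. Here 3838 genes were higher and 4935 lower (8773 in all, 47.0%), and 1459 of the higher and 703 of the lower changed at least 2-fold. CTAG2 (6.97 ± 0.09, 125.2-fold, adjusted p = 2.02e-08) and CTAG1A (6.93 ± 0.08) again rose most. They were followed, in the same ranking, by SVOP, a gene related to a synaptic vesicle protein (at least 30.2-fold higher), the monocyte chemokine CCL2 (5.68 ± 0.20), ADIRF (5.13 ± 0.54), TCF7L1 (at least 11.8-fold higher), the inflammatory cytokine TNF (4.77 ± 0.19) and the pattern receptor TLR2 (4.76 ± 0.13). TNF (chromosome 6, 31545837 to 31545896) went from −4.34 ± 0.20 to 0.43 ± 0.37. TLR2 was well above background on only 1 of the 3 control arrays, so the size and rank of its rise are rough. The same holds for ADIRF, whose dim control values were spread widely (−3.63, −5.67 and −5.26). The falls were led by those of ALDH7A1 (at least 151-fold lower), DNAJC15 (at least 29.3-fold lower), the catenin CTNNA3 (at least 10.8-fold lower), ADAM2 (−5.50 ± 0.09), SHC3 (−5.45 ± 0.14), TFF1 (−5.07 ± 0.09), the noncoding RNA UICLM (−4.52 ± 0.17) and COLCA1 (−4.44 ± 0.10).

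Against control, the other tested probe of CXCL2 and that of PARP9 did not give the same call with BHC80-1, nor did 1 of the 3 other probes of ATF3 with either isoform, or 2 (BHC80-1) and 1 (BHC80-2) of the 3 of SRRM3. In these comparisons with control the arrays of the groups did not overlap for 55.9% and 55.3% of genes, where chance gives 10%. The share of called genes that were higher, 45.4% and 43.7%, depended on the scaling. It was 55.4% and 55.6% when the 75th percentile was taken over probes detected on all arrays, and 33.9% and 25% with median centring, which moved the median of all genes to −0.16 and −0.26. With the slide as a block 9109 and 8726 genes passed. On slide 1 alone 5593 and 3493 genes passed, and on slide 2 alone 1647 and 3629. Slide 1 holds 1 BHC80-2 array, and slide 2 holds 1 control and 1 BHC80-1 array, so in these fits a lone array is assumed to vary like the arrays of the other groups. Changes correlated between the slides across genes at 0.833 for BHC80-1 and 0.795 for BHC80-2.

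**Figure D1:**
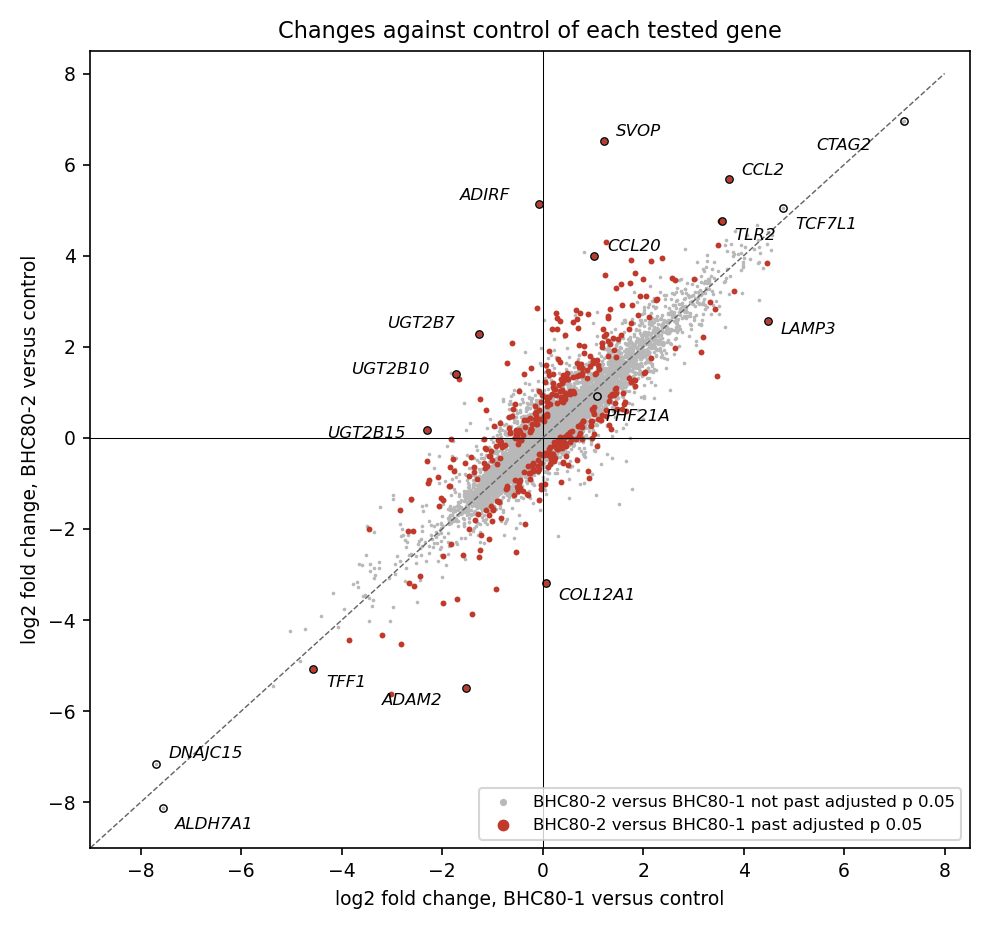
Each point is 1 of the 18659 tested genes, with its log2 fold change against control for BHC80-1 on the horizontal axis and for BHC80-2 on the vertical axis, and red points are the 416 genes that differed between the isoforms at adjusted p under 0.05. Most points lie along the dashed line of equal change (r = 0.92), while SVOP, ADIRF and the UGT2B genes lie above it and ADAM2 and COL12A1 below.

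NF-kappaB targets and cytokines were higher as lists with both isoforms at the preset correlation between genes, but not at an estimated one. Among NF-kappaB targets, 18 of 23 tested members rose and 1 fell with BHC80-1 (median 0.73, 0.65 on slide 1 and 0.81 on slide 2, adjusted p = 1.7e-05), and 19 rose and 0 fell with BHC80-2 (median 1.13, 0.87 and 1.35 by slide, adjusted p = 6.96e-08). With an estimated correlation these list calls were lost (adjusted p = 0.286 and 0.154). Adjusted over the list alone, the counts were 18 and 2, and 19 and 0. BCL3, an NF-kappaB cofactor, rose by 1.05 ± 0.06 and 1.43 ± 0.06, the inhibitor TNFAIP3 by 2.25 ± 0.13 with BHC80-1, and BIRC3 by 2.91 ± 0.12 with BHC80-2. Of 31 cytokines and chemokines 19 were tested, and IL6, IL1A and IL1B were not. Of the 19, 9 rose and 3 fell with BHC80-1 (median 1.03, 1.16 and 0.39 by slide, adjusted p = 0.012), and 10 rose and 3 fell with BHC80-2 (median 0.92, 1.64 and 1.01 by slide, adjusted p = 0.00226). Their p-values with an estimated correlation were adjusted p = 0.465 and 0.453, and the BHC80-1 call was also lost when probes had to be well above background on all arrays (median 0.09). With normexp background correction the cytokine medians were 0.18 and 0.46. TNF rose by 3.52 ± 0.19 with BHC80-1, and CCL20 by 4.00 ± 0.12 with BHC80-2. Of 26 Toll-like receptor, MyD88 and p38 components, 11 rose and 6 fell, and 12 rose and 6 fell, and the list did not pass (adjusted p = 0.147 in both). TLR2 rose by 3.56 ± 0.13 with BHC80-1, from a control group with only 1 of 3 arrays well above background, so the size is rough. TLR1 was at least 1.71-fold and at least 2.93-fold higher on the main scale. With normexp background correction the TLR1 changes were 0.24 and 0.49, and both calls were lost. Of 10 tested leukocyte markers, 1 rose and 1 fell with BHC80-1 (median −0.01, adjusted p = 0.945) and 1 rose with BHC80-2 (median 0.03, adjusted p = 0.553). Among these markers CORO1A rose by 0.41 ± 0.09 and 0.53 ± 0.09, calls lost with median centring, and CD68 changed by −0.54 ± 0.13 with BHC80-1. CD3D did not pass with BHC80-2 (0.43 ± 0.29, adjusted p = 0.275).

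Hypoxia, stress and immediate early lists were also higher at the preset correlation, and not at an estimated one. Of 22 hypoxia targets, 18 rose and 0 fell with each isoform, with medians of 1.05 (adjusted p = 7.18e-08) and 0.83 (adjusted p = 1.07e-06). With an estimated correlation these calls were lost (adjusted p = 0.426 and 0.427). The glycolytic regulator PFKFB3 rose by 2.23 ± 0.13 and 2.12 ± 0.13, the oxidase ERO1A by 1.32 ± 0.08 with BHC80-1 and ANKRD37 by 2.34 ± 0.17 with BHC80-2. Of 25 ATF4 and unfolded protein response genes, 17 rose and 2 fell with BHC80-1 (median 0.56, adjusted p = 1.35e-05), and 13 rose and 2 fell with BHC80-2 (median 0.40, adjusted p = 0.000786). These calls too were lost with an estimated correlation (adjusted p = 0.154 and 0.286). The stress transcription factor ATF3 rose by 1.74 ± 0.08 and 1.49 ± 0.08, CRELD2 by 1.18 ± 0.06 with BHC80-1, and DDIT4 by 1.36 ± 0.10 with BHC80-2. Of 29 immediate early and labile transcripts, 16 rose and 4 fell (median 0.38, adjusted p = 0.012), and 17 rose and 3 fell (median 0.54, adjusted p = 0.0032), calls lost with an estimated correlation (adjusted p = 0.427 and 0.426). In that list DUSP4 fell (−1.27 ± 0.07) with BHC80-1, while EGR1 rose by 1.67 ± 0.08 and KLF4 by 1.52 ± 0.08 with BHC80-2.

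DNA replication genes were lower as a list with both isoforms at the preset correlation, and mitosis genes with BHC80-1, but not at an estimated one. Of 29 DNA replication genes, 24 fell with BHC80-1 (median −0.55, −0.59 and −0.42 by slide, adjusted p = 8.18e-07) and 25 with BHC80-2 (median −0.61, −0.62 and −0.51 by slide, adjusted p = 1.37e-07), and none rose in limma's test. With an estimated correlation these calls were lost (adjusted p = 0.426 in both). The helicase subunit MCM6 fell (−1.06 ± 0.06 and −0.96 ± 0.06), as did the cyclin CCNE2 (−1.23 ± 0.09 and −1.27 ± 0.09). Of 27 mitosis genes, 17 fell with BHC80-1 (median −0.42, adjusted p = 0.00226, and adjusted p = 0.513 with an estimated correlation), and 10 fell with BHC80-2, where the list did not pass (median −0.19, adjusted p = 0.102). For BHC80-2 it passed without BHC80-2 array 3 (median −0.25), with no filter on dim probes and with the replicate number as a block. BIRC5 (−0.60 ± 0.08 and −0.57 ± 0.08) and CENPA (−0.68 ± 0.09 and −0.58 ± 0.09) fell. Of 25 p53 targets, 7 rose and 6 fell, and 5 rose and 5 fell (adjusted p = 0.327 and 0.476). Among them BBC3 rose by 1.64 ± 0.08 and 1.32 ± 0.08, and TP53I3 fell (−1.28 ± 0.07 and −1.38 ± 0.07).

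Neuroendocrine markers did not pass as a list. Of 30 such markers 12 were tested, of which 3 rose and 6 fell with BHC80-1 (median −0.62, −0.70 and −0.45 by slide, adjusted p = 0.277), and 3 rose and 5 fell with BHC80-2 (median −0.13, −0.63 and −0.03 by slide, −0.38 with the slide as a block, adjusted p = 0.437). The decarboxylase DDC (−3.45 ± 0.11 and −1.99 ± 0.11) and the synaptotagmin SYT4 (−2.45 ± 0.10 and −3.04 ± 0.10) fell. Of 18 tested REST target neuronal genes, 2 rose and 8 fell with each isoform (adjusted p = 0.128 and 0.104). For BHC80-2 this list passed with quantile normalization (median −0.52 against −0.38). The splicing factor SRRM3 rose by 1.76 ± 0.14 and 1.97 ± 0.14. Of 17 neural splicing regulators, 7 rose and 4 fell, and 8 rose and 4 fell (adjusted p = 0.299 and 0.222). Among these CELF4 rose by 4.00 ± 0.13 and 3.87 ± 0.13, and NOVA1 fell (−1.46 ± 0.06 and −2.00 ± 0.06). Of 19 members of the LSD1-CoREST list, 6 rose and 5 fell, and 5 rose and 5 fell (adjusted p = 0.691 and 0.913, with a median of −0.01 against a positive mean for BHC80-2), and ZMYM2 fell (−0.72 ± 0.08 and −0.80 ± 0.08).

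Of 25 androgen receptor targets, 6 rose and 10 fell with BHC80-1 (median −0.02, 0.02 and −0.26 by slide, adjusted p = 0.318), and 2 rose and 12 fell with BHC80-2 (median −0.25, adjusted p = 0.0723). The elongation factor ELL2 fell (−1.98 ± 0.06 and −2.59 ± 0.06), as did the channel TRPM8 with BHC80-2 (−1.58 ± 0.08) and the glucuronosyltransferase UGT2B15 with BHC80-1 (−2.31 ± 0.08). With BHC80-2 UGT2B15 did not pass limma's test (0.175 ± 0.081, adjusted p = 0.119). KLK3, which encodes prostate-specific antigen, fell (−1.56 ± 0.20 and −2.20 ± 0.20), and so did KLK2 (−1.03 ± 0.09 and −1.49 ± 0.09). KLK3 and KLK2 were picked after their values were seen, and the list itself did not pass with either isoform on the main scale. Over the other scalings the median of the list for BHC80-1 ran from −0.16 to 0.07. For BHC80-2 the list passed with median centring (median −0.48) and with no filter on dim probes (−0.21).

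Of 19 luminal epithelial markers, 5 rose and 6 fell, and 3 rose and 7 fell (adjusted p = 0.716 and 0.432), with KRT8 at −1.07 ± 0.09 and −1.03 ± 0.09 and ESRP2 at −0.74 ± 0.07 and −0.76 ± 0.07. Of 14 basal markers 8 were tested, of which 5 rose and 0 fell with each isoform (median 0.61, adjusted p = 0.0335, and median 0.72, adjusted p = 0.012). KRT5, KRT6A, KRT17, TP63, DSG3 and COL17A1 were on the arrays but had no tested probe, so the list result does not cover them. The BHC80-1 call was lost with the 75th percentile over detected probes (adjusted p = 0.0507), with quantile normalization (0.0942), with no filter (0.0765) and, like that of BHC80-2, with an estimated correlation (adjusted p = 0.426 in both). The cadherin CDH3 rose by 3.90 ± 0.13 and 4.04 ± 0.13, and the integrin ITGB4 by 1.02 ± 0.11 and 1.101 ± 0.113. Of 22 epithelial-mesenchymal transition genes 15 were tested, and ZEB1, ZEB2 and TWIST2 were not. Of the 15, 8 rose and 0 fell with BHC80-1 (median 0.27, adjusted p = 0.0664), and 9 rose and 1 fell with BHC80-2 (median 0.40, adjusted p = 0.0134, and adjusted p = 0.426 with an estimated correlation). SNAI1 rose by 0.60 ± 0.07 and 0.68 ± 0.07, S100A4 by 0.82 ± 0.10 and 0.89 ± 0.10, calls that normexp background correction ended, and VIM by 2.71 ± 0.53 and 3.48 ± 0.53. VIM read 2.66 on control array 1 against 0.61 and 0.29 on the other control arrays, and COL1A1 −0.69 against −1.81 and −1.74. Of 15 fibroblast and stromal markers 6 were tested, of which 3 rose and 0 fell with each isoform (adjusted p = 0.191 and 0.145). ACTA2 rose by 1.24 ± 0.16 and 1.15 ± 0.16, MYL9 by 1.38 ± 0.24 with BHC80-1, and COL1A1 by 1.17 ± 0.26 with BHC80-2. Without control array 1 the fibroblast list passed (medians 0.81 and 0.80, against 0.59 and 0.57 with it), and so did the transition list for BHC80-1 (median 0.27), which also passed with median centring (0.13) and with probes well above background on all arrays (0.44).

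Of 34 interferon-stimulated genes, 8 rose and 18 fell, and 9 rose and 12 fell, and the list did not pass (adjusted p = 0.148 and 0.748). HERC5 rose by 2.47 ± 0.09 and 2.57 ± 0.09, PARP9 fell with BHC80-1 (−1.37 ± 0.09) and IFI6 with BHC80-2 (−1.17 ± 0.08). Of 23 cholesterol synthesis genes, 6 rose and 5 fell, and 5 rose and 8 fell (adjusted p = 0.549 and 0.645), and for BHC80-1 the median was −0.01 while the mean and the test were positive. STARD4 rose by 1.21 ± 0.07 and 0.91 ± 0.07.

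**Figure D2:**
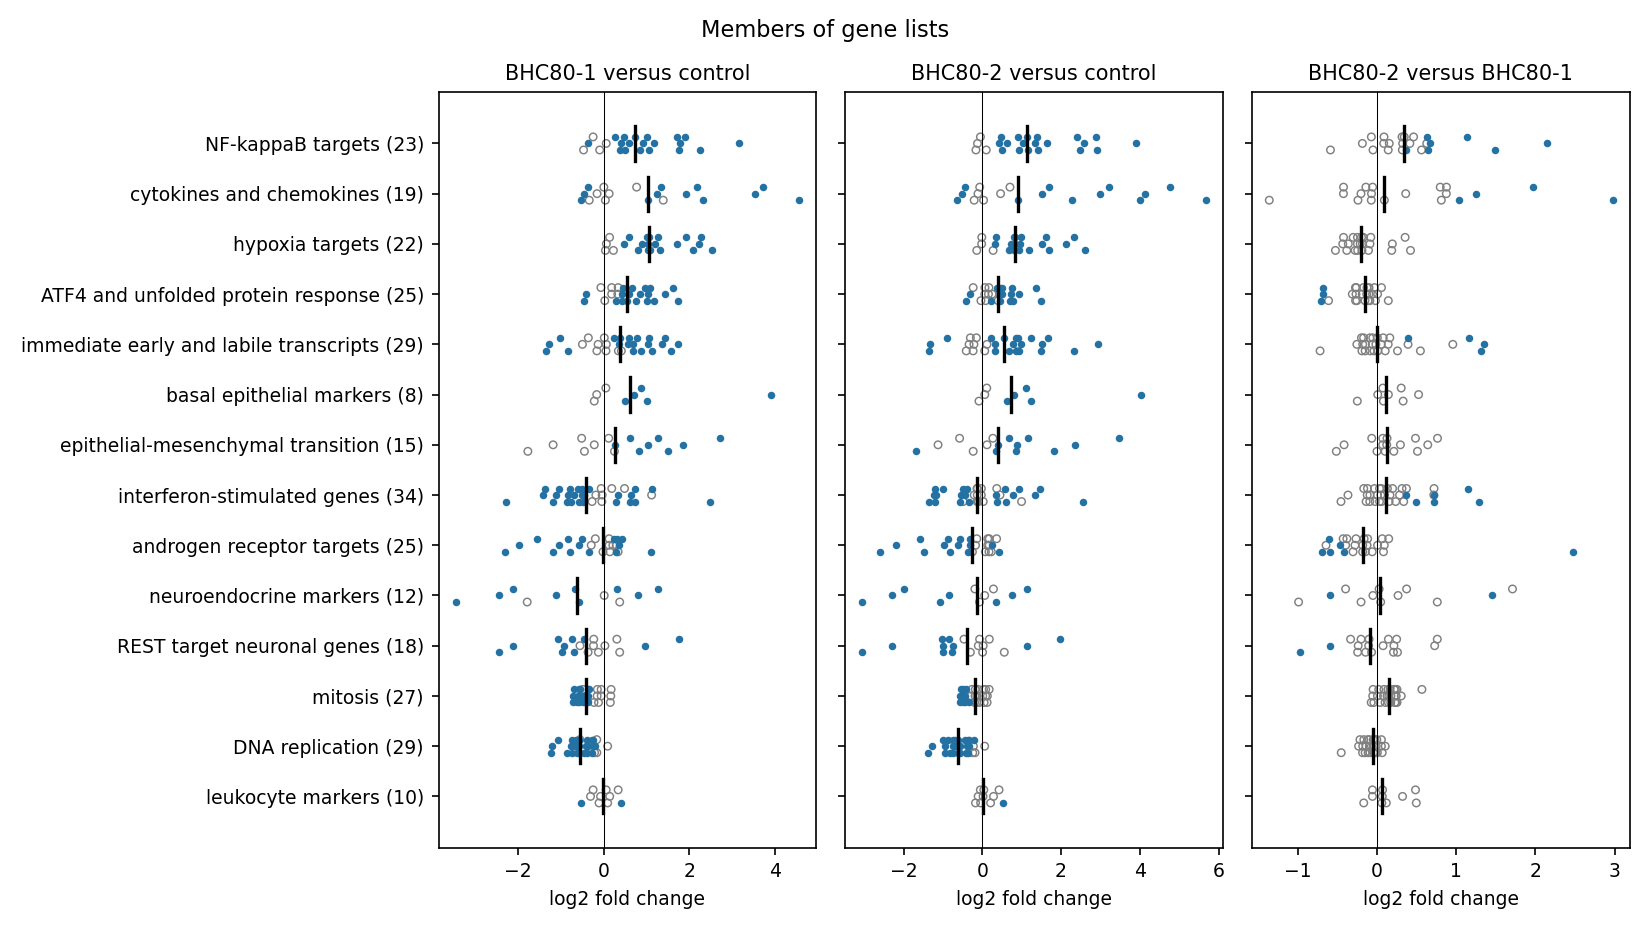
Log2 fold changes of the tested members of 14 gene lists, whose numbers stand in parentheses, in the 3 comparisons, with filled points for members past adjusted p 0.05, open points for the others and a black bar at the list's median. NF-kappaB and hypoxia targets lie mostly above 0 against control, and DNA replication genes mostly below.

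The changes of the isoforms against control were alike. Across the 18659 genes they correlated at r = 0.92 (Spearman's rho 0.897), where unchanged groups that share the control arrays gave a mean of 0.499 (0.411 to 0.573) in 1000 simulations. The covariance was 0.542 against a simulated mean of 0.0237. Both isoforms were higher than control for 3329 genes and lower for 4222, where independent lists would share 823.6 and 1273.2. Of the 7572 genes called in both comparisons 99.7% had the same sign and 21 had opposite signs. The comparisons share their control arrays, which cannot be split, so part or all of this excess may come from them. The simulations held only the spread between arrays. They do not cover control cultures that differ from both BHC80 cultures for reasons other than the isoforms.

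The comparison of BHC80-2 with BHC80-1 asks where the isoforms differ. Here 230 genes were higher and 186 lower with BHC80-2 (416 in all, 2.2%), 80 and 30 of them at least 2-fold, and the arrays did not overlap for 27.7% of genes, where chance gives 10%. SVOP (chromosome 12, 109304691 to 109304740) rose at least 29.8-fold and ADIRF by 5.19 ± 0.54. The ADIRF values with BHC80-1 were dim and spread widely (−5.69, −4.77 and −4.28), so the size of that rise is rough. The glucuronosyltransferase genes UGT2B7 (3.55 ± 0.10, adjusted p = 3.24e-06), UGT2B10 (3.13 ± 0.09), UGT2B11 (2.96 ± 0.09) and UGT2B15 (2.48 ± 0.08) were higher, as were CCL20 (2.98 ± 0.12) and the tryptophan dioxygenase TDO2 (at least 2.58-fold). Lower with BHC80-2 were ADAM2 (−3.96 ± 0.09), the collagen COL12A1 (−3.25 ± 0.13), CTNNA3 (at least 1.33-fold), the homeobox gene LHX9 (−2.11 ± 0.14), CBLN2 (−1.97 ± 0.07), LAMP3 (−1.92 ± 0.23) and KCNJ2 (at least 1.25-fold). Of these, TDO2, CTNNA3, LHX9, LAMP3 and KCNJ2 lost their calls with normexp background correction, and KCNJ2 also without any 1 of the BHC80 arrays other than BHC80-2 array 3 (−1.94 to −1.55). KCNJ2 lost its call with the slide as a block (−1.70) too, and was −0.88 on slide 1 against −2.49 on slide 2. Median centring, quantile normalization, no filter, a fit of only the groups compared and the replicate number as a block also ended it.

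NF-kappaB targets were higher with BHC80-2 than with BHC80-1 for 7 of 23 members and lower for 0 (14 and 1 adjusted over the list alone, median 0.35, adjusted p = 1.08e-10, and adjusted p = 0.154 with an estimated correlation). ICAM1 rose by 2.14 ± 0.19, a call that normexp background correction ended, and BIRC3 by 1.14 ± 0.12. Among cytokines and chemokines 4 rose and 0 fell (median 0.10, adjusted p = 0.00228, and 0.453 with an estimated correlation), with CCL2 at 1.97 ± 0.20. Of 34 interferon-stimulated genes 6 rose and 0 fell (median 0.12, adjusted p = 9.58e-05, and adjusted p = 0.29 with an estimated correlation). OAS2 rose by 1.15 ± 0.18, a call lost without any 1 of the BHC80 arrays other than BHC80-2 array 3 (0.99 to 1.22), with normexp background correction (0.37), with the mean of the gene's probes (0.52), with no filter, in a fit of only the groups compared and with the replicate number as a block. RSAD2 (1.29), also 1 of the 6, was below the background limit in both groups, and normexp background correction ended its call (0.125). Androgen receptor targets were lower as a list (1 rose and 5 fell of 25, median −0.18, adjusted p = 2.33e-05, and adjusted p = 0.154 with an estimated correlation), with ELL2 at −0.61 ± 0.06 and KLK2 at −0.46 ± 0.09 (adjusted p = 0.0433), while UGT2B15 rose. The ATF4 list was lower (0 rose and 3 fell, median −0.15, adjusted p = 2.33e-05, and adjusted p = 0.154 with an estimated correlation), with CRELD2 at −0.68 ± 0.06 and the chaperone HSPA5 at −0.70 ± 0.08.

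In 3 lists no single member passed in limma's test though the list did. Mitosis genes were higher (median 0.15, adjusted p = 0.000249), and hypoxia targets (median −0.20, adjusted p = 0.00226) and cholesterol synthesis genes (median −0.14, adjusted p = 0.000264) were lower. These calls were lost with an estimated correlation (adjusted p = 0.465, 0.545 and 0.154). Among immediate early transcripts 4 rose (adjusted p = 0.219), with EGR1 at 1.32 ± 0.08 and DUSP6 at 1.16 ± 0.10, and among Toll-like receptor components 3 rose (adjusted p = 0.232), with TLR2 at 1.19 ± 0.13 and TLR3 at 0.90 ± 0.15. TLR2 and TLR3 lost their calls with normexp background correction, and TLR3 also without any 1 of the BHC80 arrays other than BHC80-1 array 2 (0.79 to 0.97), with the slide as a block (0.89), with median centring (0.81) and with no filter. Neuroendocrine markers (1 rose, 1 fell, adjusted p = 0.314), REST targets (0 and 2, adjusted p = 0.486), neural splicing regulators (0 and 1, adjusted p = 0.713) and luminal markers (0 and 1, adjusted p = 0.432) did not pass as lists. In these lists DDC rose by 1.46 ± 0.11, and SYT4 (−0.59 ± 0.10), KCNH2 (−0.97 ± 0.12), NOVA1 (−0.54 ± 0.06) and KRT19 (−0.56 ± 0.09) fell. SYT4 lost its call without any 1 of the 6 BHC80 arrays (−0.65 to −0.55), and KRT19 without any 1 other than BHC80-1 array 2 (−0.56 to −0.49). Both also lost it with no filter and with the replicate number as a block, KRT19 with normexp (−0.48) and median centring (−0.65), and NOVA1 with median centring (−0.63). Other tested probes of DDC, KCNH2, NOVA1 and OAS2 did not give the same call between the isoforms. The LSD1-CoREST list (adjusted p = 0.299), DNA replication (0.101), p53 targets (0.432), the transition list (0.106), basal (0.148), fibroblast (0.962, with a median of −0.02 and a positive test) and leukocyte markers (0.125) had 0 members past limma's threshold and did not pass. DNA replication passed without BHC80-1 array 2 or 3 or BHC80-2 array 1 or 3 (medians −0.10 to −0.07), basal markers without BHC80-2 array 3 (0.19) and leukocyte markers without BHC80-1 array 3 (0.16). DNA replication also passed with normexp, no filter and the replicate number as a block, and the transition list with normexp and in a fit of only the groups compared.

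The count of 416 fell when any BHC80 array was left out. It was 165, 163 and 187 without BHC80-1 array 1, 2 or 3, and 170, 219 and 187 without BHC80-2 array 1, 2 or 3. With the slide as a block it was 371, of which 315 were among the 416. In limma fits of slide 1 or slide 2 alone, with 1 BHC80-2 array or 1 BHC80-1 array, it was 0, which says little about the slide, with 1428 and 1726 genes at an unadjusted p under 0.05 against 2777 with all arrays. Changes correlated between the slides across genes at 0.338.

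**Figure D3:**
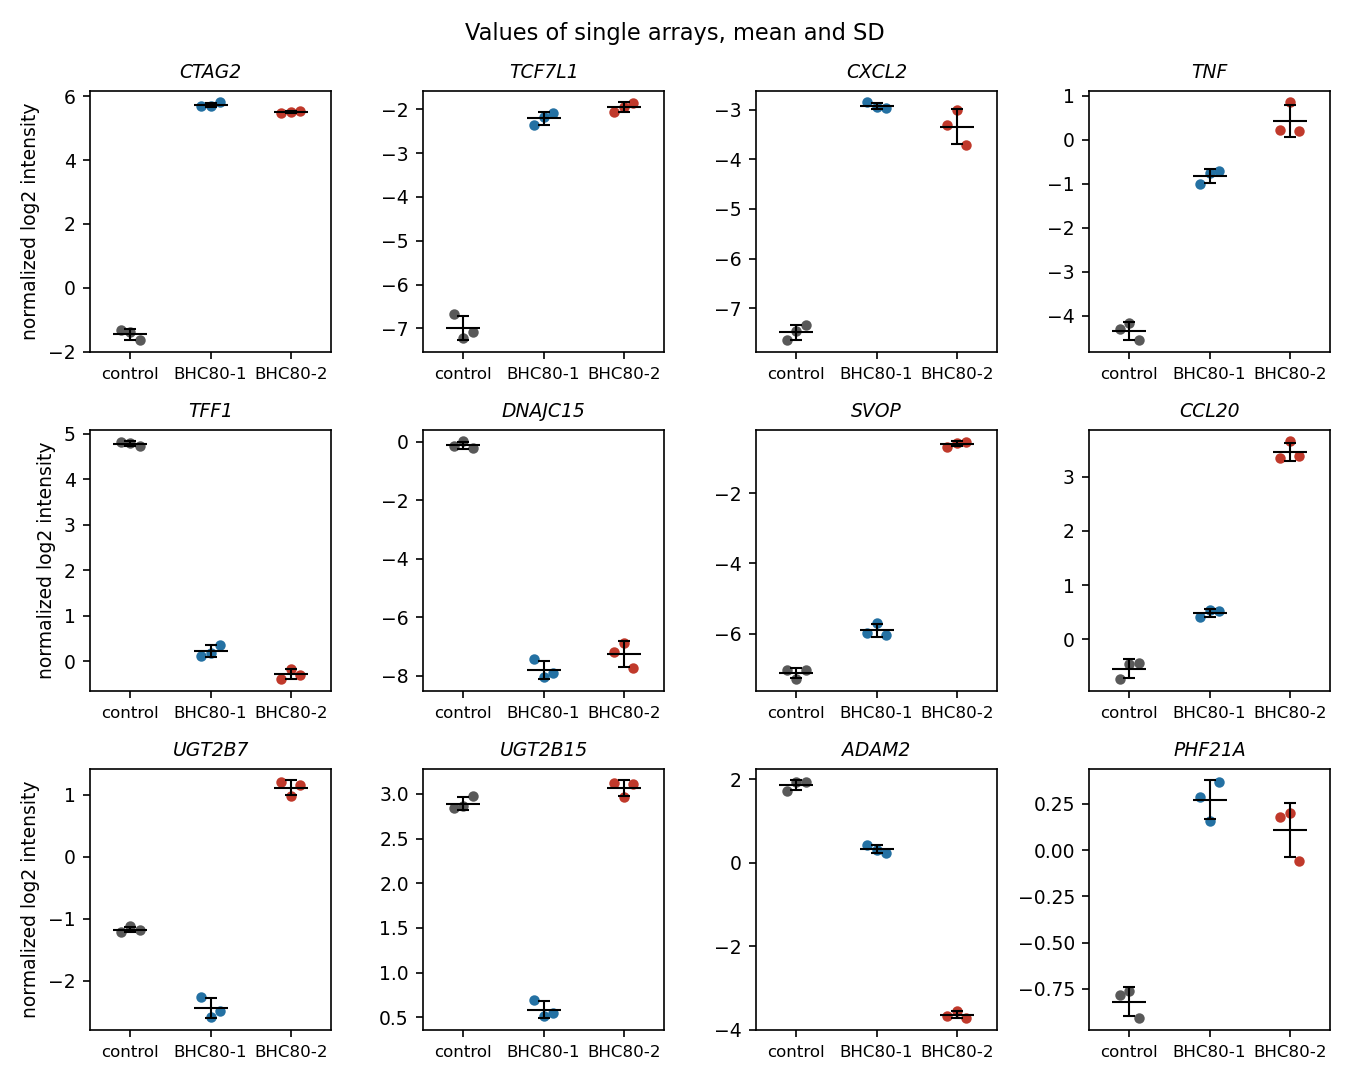
Normalized log2 intensities of 12 genes on the 3 arrays of each group, with a bar at the mean and whiskers of 1 SD, on a separate vertical scale for each gene that need not include 0. CTAG2, TCF7L1, CXCL2 and TNF are higher and TFF1 and DNAJC15 lower with both isoforms, while SVOP, CCL20, UGT2B7 and ADAM2 also differ between them.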

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

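The slide test of this part was chosen before the results were seen, while the naming of the gene family was not. In 21 genes the isoforms changed in opposite directions against control, with adjusted p under 0.05 in both comparisons with control and in the test of the difference itself (3 arrays per group). They are singled out because the groups' changes differ. Given as the difference BHC80-2 minus BHC80-1, 13 were higher with BHC80-2: UGT2B7 (3.552; −1.27 with BHC80-1 and 2.29 with BHC80-2 against control), UGT2B10 (3.132), UGT2B11 (2.964), PCDH20 (2.357; −0.72 and 1.64), DOK6 (1.751; −1.14 and 0.62), SPTLC3 (1.31), FCGBP (1.213), DUSP6 (1.159), DHRS2 (1.129), S100P (1.103), VAV3 (0.772), MAGEA1 (0.706) and SOD3 (0.595). The other 8 were lower with BHC80-2: LOC100506342 (−0.554), SAP25 (−0.856), RGS2 (−0.92), DENND1B (−0.965), ORAI3 (−1.1), TIAM1 (−1.171), BEX1 (−1.346; 0.37 and −0.98) and ACOX2 (−1.613; 0.89 and −0.72). Some of these calls of a difference were lost without 1 array: LOC100506342 without any 1 BHC80 array other than BHC80-1 array 3 (−0.57 to −0.49), MAGEA1 without BHC80-1 array 1 or 2 or BHC80-2 array 1 or 3 (0.67 to 0.72), SOD3 without BHC80-1 array 1 or 2 (0.58 in both) and RGS2 without BHC80-1 array 2 (−0.86). With normexp background correction DOK6 (0.50), TIAM1 (−0.60), VAV3 (0.54) and LOC100506342 (−0.44) lost theirs. LOC100506342, MAGEA1 and SOD3 also did so with median centring and with no filter, and MAGEA1 and SOD3 with the replicate number as a block. Changes on each slide alone were of similar size, for example 3.58 and 3.57 for UGT2B7 and −1.65 and −1.64 for ACOX2. None of the 21 passed there in limma's test (1428 and 1726 of all genes at an unadjusted p under 0.05), but each slide holds only 1 array of 1 isoform, so this says nothing about the slide.

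Against the slide as the whole cause of the differences between the isoforms, 92.7% of the 110 genes changed at least 2-fold kept their call with the slide as a block. Of the 10 splits of the 6 BHC80 arrays 1, the real one, gave as many genes (416, highest other 1), and 10 splits are too few for a share under 0.05. The UGT2B genes are close paralogs, so their probes may share signal, and a second, dim UGT2B7 probe did not pass (0.30 ± 0.31, adjusted p = 0.779). A difference between the isoforms stays open as an untested biological explanation, as does a difference between the cultures.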

How the results depend on the processing

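The fits of each slide alone were chosen after the data were seen. Of 200 gene results over 23 settings, 3722 values kept direction and side of the threshold, 13 gained a call, 224 lost one and 3 reversed. Of 63 list results over 24 settings, 1266 stayed, 25 gained, 32 lost and 0 reversed. The estimated correlation ended all 24 list calls, to 0 in camera, with 9 of 63 at an unadjusted p under 0.05. The smallest adjusted p in camera was then 0.154. The estimate lay above the preset 0.01 for hypoxia targets (0.468), mitosis (0.348), DNA replication (0.332), cytokines (0.231) and NF-kappaB targets (0.128). It did so less for immediate early transcripts (0.085) and the ATF4 list (0.053). The preset p-values of these lists thus rest on a lower correlation than the one estimated. A higher correlation is not the whole reason for the losses. For cholesterol synthesis genes between the isoforms the estimate was −0.012, below the preset 0.01, yet camera's adjusted p went from 0.000264 to 0.154. These losses thus do not show that the lists were unchanged.

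The count of 416 between the isoforms was 189 with median centring, 164 with normexp, 142 with no filter, 675 with an intensity trend, 192 with the replicate number as a block and 110 at 2-fold. The cause was not tested, except that a fold threshold adds a condition. Without 1 array it ran from 163 (without BHC80-1 array 2) to 219 (without BHC80-2 array 2), with 165 and 187 without BHC80-1 array 1 or 3 and 170 and 187 without BHC80-2 array 1 or 3, where fewer arrays were fitted. The counts against control were 2151 and 2162 at 2-fold. On slide 1 alone counts were 5593, 3493 and 0, and on slide 2 alone 1647, 3629 and 0, in limma fits where slide 1 had 1 BHC80-2 array and slide 2 had 1 control and 1 BHC80-1 array, assumed to vary like the other groups (1428 and 1726 genes at an unadjusted p under 0.05 for the zeros). The correlation of changes was 0.81 with no filter and 0.89 on either slide alone, against 0.92. The cause was not tested.

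LOC100506342 reversed between the isoforms with the mean of the probes of a gene (0.15, against −0.554). LGALS1, not called with all arrays (−0.12 and −0.02), was 0.477 and 0.576 without control array 1, whose value (1.52) lay above those of the other control arrays (−0.22 and −0.32), and −0.446 and −0.346 without control array 3. CCDC80 lost its BHC80-1 call (1.43) without control array 2 (1.103) or 3 (1.09) or any BHC80-1 array, with median centring, quantile normalization, no filter, only the groups compared or the replicate number as a block, and gained one with BHC80-2 without control array 1 (1.75). Normexp ended 19 gene calls, and the cause was not tested. Between 56.7% and 65.3% of spots were well above background, and folds against a group with no such array are lower bounds.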

Other observations

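The tests of chance placement, of fewer copies of 5 chromosomes and of more leukocyte RNA were chosen after the results were seen, as were the gene families. Medians against control with BHC80-1 and BHC80-2 were −2.18 and −2.05 for 12 PCDHB genes, 1.72 and 1.28 for 8 HOXA genes, 0.85 and 1.02 for 7 HOXB genes, 0.80 and 0.94 for 23 transcripts named HLA, 1 of them antisense, and 1.30 and 1.04 for 11 metallothionein genes and pseudogenes. In these sets 1 metallothionein pseudogene, MT1DP, fell (−1.31 and −1.36), as did 1 HOXB gene with BHC80-2. Probes of close paralogs may share signal, so the members of a family are not separate measurements. The HLA-B probe (chromosome 6, 31321653 to 31321712) overlaps that of HLA-C (31321644 to 31321703). The directions of the medians held under 3 other scalings and normexp. With normexp the medians were −0.88 and −0.74 for PCDHB, 1.02 and 0.90 for HOXA, 0.32 and 0.46 for HOXB with 3 members higher in each, 0.59 and 0.76 for HLA and 1.28 and 1.02 for metallothioneins. Genes at least 1 log2 unit from the mean of the other 2 control arrays, themselves within 0.5, numbered 71 higher and 69 lower on control array 1, 386 and 37 on array 2, and 74 and 103 on array 3.

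Many genes differed between control and both BHC80 groups. Against scaling as the cause, the lowest count over 3 other scalings and normexp background correction was 6607, with normexp (8773 reported). Over the scalings alone the lowest was 7580 (BHC80-1, median centring). Without control array 1 the count was 9035 (8818 reported). Windows of 51 neighbouring genes with a median of 0.25 or more in size held 13.9% (BHC80-1) and 16.1% (BHC80-2) of changed genes. Shuffled genes gave at most 0.7%. These shares argue against copy number of segments shifted that far as the cause of most changes. They cannot decide on smaller shifts, such as the BHC80-1 medians of −0.21 on chromosome 2 and −0.17 on chromosome 14. Chance placement is also argued against, since the medians of 5 of 23 chromosomes with BHC80-1 and 6 with BHC80-2 (chromosome 21 as well, −0.17) lay beyond 100 shuffles, as did 4 between the isoforms (chromosome 3 at −0.11). On chromosomes 2, 12, 13, 14 and 18 the quartiles lay below those of other chromosomes (upper quartile by −0.159 at the nearest, lower by −0.238). These 5 were picked after their low medians were seen in the same data, so their quartiles are no separate support. For the genes on them, fewer copies in the BHC80 than in the control cultures may contribute. The data cannot tell which cultures had changed. No DNA was measured, and 21.2% and 21.7% of changed genes lie on these 5 chromosomes, which hold 17.9% of genes. For each comparison 1 of 10 splits, the real one, gave as many genes (8818 with highest other 2, 8773 with highest other 3), too few splits for a share under 0.05, and BHC80 overexpression stays open beside other differences between the cultures.

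Cytokine and NF-kappaB lists were higher with both isoforms at the preset correlation, and not at an estimated one (adjusted p = 0.465 and 0.453 for cytokines, 0.286 and 0.154 for NF-kappaB targets). More leukocyte RNA in the BHC80 cultures is argued against by the leukocyte markers' medians of 0.03 (SD 0.24) and −0.01 (SD 0.29), against NF-kappaB medians of 1.13 and 0.73. Leukocyte RNA as such stays open, since 9 of 15 markers were well above background on all 6 BHC80 arrays, which meets the bound set beforehand, but 7 of these 9 also were on all 3 control arrays, so the test does not separate the groups. BHC80 overexpression was not tested as the cause apart from the cultures.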
